A study of Bombus terrestris with 25 samples.

How the data were processed

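The series measured polyA RNA from the eviscerated abdomen with attached fat bodies of single queens of the buff-tailed bumble bee, Bombus terrestris. It held 25 libraries in 5 groups of 5 queens, and each library came from 1 queen. The groups were young mated queens of 5 to 10 days, queens of that age sampled 24 h after a pair of anaesthesias with pure CO2, queens at the end of a diapause of 9 to 10 weeks at 4 C, and egg-laying colony founders after each treatment. The founders were sampled about 1 month after the treatment, at 1.5 months of age after CO2 and at 4 months after diapause. The sample labels gave diapausing queens an age of 3 months and the series text 2.5 months. Mated and CO2-treated queens had the same age and neither had a cold period. In the other comparisons age or conditions of keeping changed together with the group and could not be tested apart from it.

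The submitters' processing notes named Trimmomatic, TopHat and DESeq, with no version. The deposited table held raw read counts, whole numbers that the authors had made per exon-sized interval of the genome, with 1 column per library. The genome build, the counting tool and the strand setting are not given in the sources used here. Intervals were named by scaffold, start, end and transcript accession. Starts were read as counted from 0, by lengths and not positions, from 13355 intervals whose transcript accession was named in a deposited gene model. Of these, 7598 then had the length of a coding exon of that model, against 368 when starts were counted from 1. The 22679 intervals carried 4173 transcript accessions of 3861 genes, and counts were summed per gene. Of the counts, 0.29% lay in 147 intervals off the main scaffold of their gene, and 74 genes had intervals on more than 1 scaffold. A reference table of RefSeq genes matched 3534 of the 3861 genes and was used only for names.

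The table covered part of the transcriptome. It held 2312 of the 6344 accessions named in the deposited gene models, 36.4%, and the rule by which its intervals had been chosen is not given in the sources used here. A library's total in the table is therefore not its sequencing depth, CPM, counts scaled to a common library total, are relative to the counts of the table, and adjusted p values hold for the genes of this table. Totals ran from 534806 in CO2-treated replicate 3 to 4057781 in founder post diapause replicate 3. Mated replicate 2 had 586405 and the other 23 libraries at least 2432559. In an F test of any difference among the 5 groups, 2996 of the tested genes, 79.0%, passed an adjusted p of 0.05.

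Gene counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The edgeR filter filterByExpr, with a minimum count of 10 and a minimum total of 15, kept 3793 genes and removed 68. All 25 libraries entered a single edgeR quasi-likelihood fit with TMM factors and a term per group, which left 20 residual degrees of freedom. The common dispersion gave a coefficient of variation between queens of 51.4%. The 6 comparisons were contrasts of this fit, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. A log2 fold change stands with its standard error (SE). The difference between the routes to founder was tested as the change from diapause to founder less the change from CO2 treatment to founder. A gene counted as apart in diapause when it was called in the same direction against each of the 4 other groups. Logarithms of CPM for principal components and list tests used a prior count of 2.

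Gene lists were fixed before the data were examined, as search patterns on product names. There were 24 lists: yolk and storage proteins, fatty acid and triglyceride synthesis, lipid breakdown, glycogen, trehalose and polyol metabolism, oxidative phosphorylation, heat shock proteins and chaperones, antioxidant enzymes, cytochrome P450s and UDP-glycosyltransferases, insulin, TOR and FOXO signalling, juvenile hormone and ecdysteroid pathway, immune effectors and receptors, cell cycle and DNA replication, cytosolic ribosomal proteins, cuticle and chitin, proteasome, endoplasmic reticulum secretion, circadian clock, chemosensory and odorant binding proteins, and markers of muscle, germ line and ovary, neuron, gut, hemocyte, and oenocyte and epidermis. Lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The test fry was run beside it, which asks whether a list's members changed on balance and does not compare them with other genes. The list of oenocyte and epidermis markers held the 14 fatty acyl-CoA reductases. The pattern of the immune list covered recognition and signalling genes beside effectors, and caught the NF-kappa-B inhibitor cactus-2. Patterns also caught members outside a list's meaning. The gut list held a chymotrypsin inhibitor, the neuron list a GABA receptor-associated protein and general syntaxins, the insulin list an insulin gene enhancer protein, an mRNA-binding protein, acid labile subunits and ribosomal protein S6 kinases of the alpha and delta types, and the fatty acid list shared its elongases with the oenocyte list.

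The same fixed rule named the genes. It took the 5 genes with the largest rise and the 5 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between the groups' queens. It added 2 members each of up to 10 lists with called members, the most abundant member of each list of other cell types, and the 5 genes with the smallest adjusted p in each direction for overlaps and route differences. Vitellogenin, hexamerins, Krueppel homolog 1, methoprene-tolerant, juvenile hormone epoxide hydrolase, forkhead box O, insulin-like receptor, PEPCK, fatty acid synthase, catalase and superoxide dismutases were to be given whatever their result. Krueppel homolog 1, methoprene-tolerant, fatty acid synthase and catalase were not found in the table and were not analysed here.

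Genetic lines 296, 207, 191 and 141 were present in every group, line 51 in all but the mated group and line 426 in the mated group alone. The line was tried as a replicate block. After removal of group means, 46 pairs of libraries of the same line in different groups had a median correlation across genes of 0.065, and 204 pairs of different lines one of -0.016. Of the same-line pairs, 21 lay over 0.1, and 9 of the 25 libraries were best correlated with a library of their own line.

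Alternatives fixed in advance were relative log expression factors, the DESeq2 Wald test, no low-count filter, the line as block, a fit of the compared groups alone, and leaving out each queen in turn. Alternatives chosen after seeing the data left out the 2 shallow libraries, or these and diapause replicate 1, or took only intervals of the main scaffold, or the interval with the most counts per gene. Overlap with the shared mated controls was set beside 50 simulated draws of unchanged groups and beside 20 ways of splitting the controls. The fit was tested on simulated data: of 50 genes changed 4-fold, 70% were recovered between diapause and mated queens, 66% between founders and diapause queens and 82% between the founders, and 14%, 12% and 24% at 2-fold. With no gene changed, 0 genes were called in each of the 6 comparisons. Up to 100 other splits of the libraries were run per comparison. No library was left out of the values given first.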

Results

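The data were read counts for 3793 tested genes in the eviscerated abdomen with attached fat bodies of 25 queens, in 5 groups of 5: mated, CO2-treated, diapause, founder post CO2 and founder post diapause. Totals in the table ran from 534806 to 4057781 counts per library. The first principal component held 61.6% of the variance between libraries and the second 10.1%. All 10 founder libraries lay at positive values of the first component, from 5.85 to 104, and the other 15 at negative values. Of the 25 libraries, 3 stood apart. Diapause replicate 1 lay at -4.09 on the first component, against -45.7 to -73.5 for the other 4 diapause libraries. Mated replicate 2 and CO2-treated replicate 3, the 2 shallow libraries, were nearly alike: thinned to 534806 counts, they had a chi-square per degree of freedom of 2.43, against at least 6.01 in the other pairs of libraries. The number of genes called in each comparison is therefore also given without the 2 shallow libraries and without these and diapause replicate 1, and members called in gut and camera-called lists without all 3 libraries where that count moved by over 1.5 times.

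**Figure D1:**
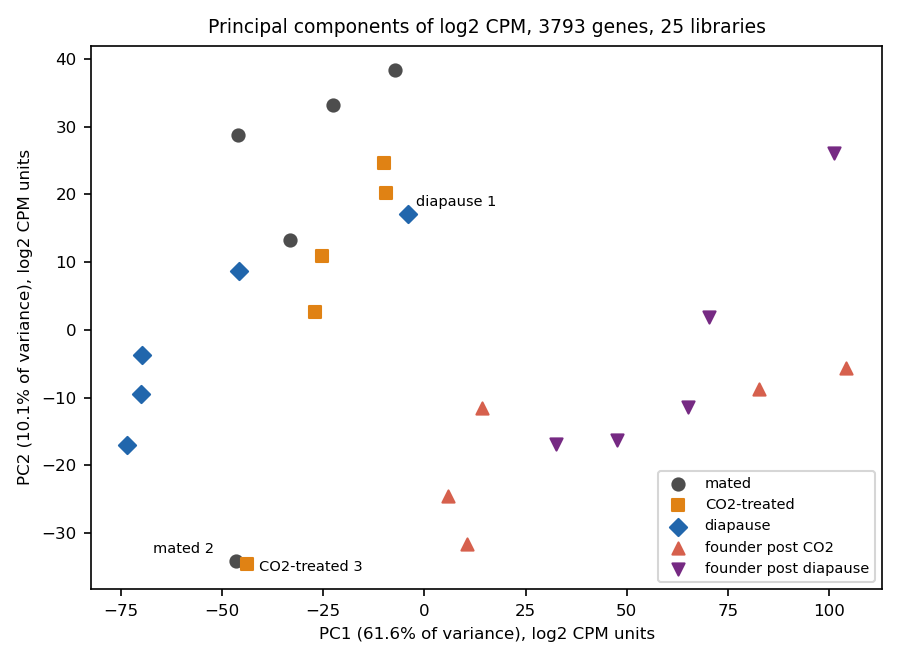
Each point is 1 of 25 libraries, placed by the first (x, 61.6% of variance) and second (y, 10.1%) principal component of log2 CPM, with shape and colour by group. Founders lie at positive x, the other queens at negative x, and diapause replicate 1 lies among mated and CO2-treated queens.

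**Figure D2:**
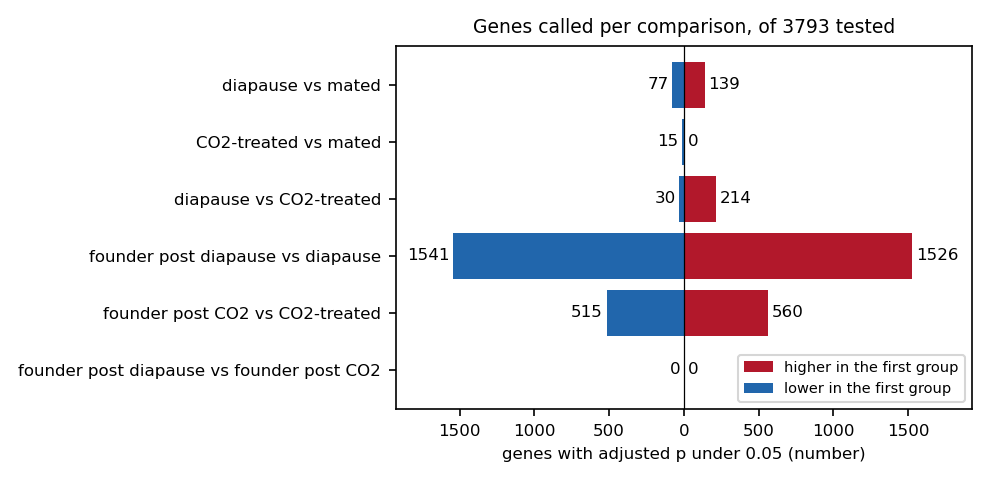
Bars give the number of genes called in each comparison by edgeR at an adjusted p under 0.05, higher (right) or lower (left) in the first group named, of 3793 tested. The change from diapause to founder has 1526 higher and 1541 lower, and the comparison of the founders has 0.

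What distinguishes a queen at the end of the cold from a young mated queen was asked first. Cryptochrome-1-like (LOC100647270), of a family of circadian clock proteins and light receptors, rose by 2.66 ± 0.44 on the log2 scale (SE, n = 5 and 5). Its mean was 702 ± 325 CPM (SD) in diapause and 111 in mated queens, and 4 of 5 diapause queens had at least 749.8 CPM, while diapause replicate 1 had 132.8. Tyrosine aminotransferase-like (LOC100647939), which begins tyrosine breakdown, rose by 2.94 ± 0.53, and the cell division control protein 6 homolog (LOC100644374), a DNA replication licensing factor, by 2.70 ± 0.47. Of 14 fatty acyl-CoA reductases, enzymes that make fatty alcohols, 0 rose and 7 fell, a family counted after its values were seen, with log2 fold changes of -6.06 ± 0.93 (LOC100647284), -5.77 ± 0.95 (LOC100647644), -3.75 ± 0.73 (LOC100651977) and -2.20 ± 0.47 (LOC100648083) in 4 of them. The calls of these 4 and of the 3 genes named before had an edgeR adjusted p of at most 0.00700 and were kept with the line as block.

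Other genes with lower values in diapause were alkaline phosphatase-like (LOC100642860, log2 -2.96 ± 0.55), the alpha-methyldopa hypersensitive protein-like gene (LOC100648451, -3.56 ± 0.75, or -2.55 without mated replicate 2), the mitochondrial 2-oxoglutarate/malate carrier (LOC100649472, -2.62 ± 0.43), cytochrome P450 305a1-like (LOC100647578, -2.21 ± 0.36) and UDP-glucuronosyltransferase 2C1-like (LOC100646290, -1.92 ± 0.33). The larval cuticle protein LCP-17-like gene (LOC100643233) rose by 3.21 ± 0.72 with an edgeR adjusted p of 0.00950, or 0.109 with the line as block, and only diapause replicates 3 and 4 had over 50 CPM. The block also ended the calls of a pair of elongases (LOC100649395, log2 -2.39, adjusted p = 0.0243, block 0.313; LOC100642650, -1.92, 0.0253, block 0.0593) and of the NF-kappa-B inhibitor cactus-2 (1.40, 0.0175, block 0.154), all by edgeR. The first elongase lost its call without mated replicate 1 or 5 or diapause replicate 2, 4 or 5, the second without mated 2 or 4 or diapause 2, 3, 4 or 5, and cactus-2 without mated 1, 3, 4 or 5 or diapause 2 or 3. Vitellogenin-6-like (LOC100643258), named by likeness to a yolk precursor, had a log2 fold change of 1.64 ± 0.84 and was not called (edgeR adjusted p = 0.243). Whether it is the main yolk gene of this species was not tested. Neither hexamerin-like storage protein gene was called, at log2 -3.40 ± 1.17 for LOC100650745 (0.0790) and -1.53 ± 0.49 for LOC100650380 (0.0632), both edgeR adjusted p. LOC100650745 was called without mated replicate 2, diapause replicate 1 or founder post CO2 replicate 2, and LOC100650380 without diapause replicate 1, founder post CO2 replicate 1 or 3 or founder post diapause replicate 5.

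By list, 1 of 30 oenocyte and epidermis markers rose and 9 fell, or 2 and 10 adjusted over the list alone (camera adjusted p = 2.56e-06, or 0.195 with an estimated correlation). The 9 that fell include the 7 fatty acyl-CoA reductases counted above, so the list is not separate evidence. Of 19 genes of fatty acid and triglyceride synthesis 0 rose and 3 fell, or 4 fell adjusted over the list alone (camera 0.00292; adjusted p = 0.212 with an estimated correlation). Of 20 cytochrome P450s and UDP-glycosyltransferases 4 fell, or 5 adjusted over the list alone (camera 0.00935; adjusted p = 0.400 with an estimated correlation). No member of the 27 proteasome genes was called, over the list alone either, while their median was -0.59 (camera adjusted p = 2.56e-06; adjusted p = 0.642 with an estimated correlation). The 37 oxidative phosphorylation genes had 0 calls and a median of -0.37 (camera 0.00935, or 0.371 with the line as block; adjusted p = 0.937 with an estimated correlation). Adjusted over the list alone, 2 of 3 yolk and storage proteins were lower and 5 of 16 insulin, TOR and FOXO genes higher, in lists that camera did not call. Antioxidant enzymes (camera 0.0118, block 0.155; adjusted p = 0.876 with an estimated correlation) and endoplasmic reticulum secretion (camera 0.0394, block 0.371; adjusted p = 0.937 with an estimated correlation) had 0 calls as well. Without the 2 shallow libraries and diapause replicate 1 17 of 27 proteasome, 12 of 37 oxidative phosphorylation and 4 of 12 secretion genes were lower and 0 higher, and higher and lower genes numbered 1 and 9 of 25 for antioxidant, 1 and 9 of 20 for cytochrome P450 and UDP-glycosyltransferase, 1 and 10 of 19 for fatty acid and 3 and 17 of 30 for oenocyte and epidermis genes. The 3' to 5' coverage (median log2 ratio less the gene's mean, over 775 genes) moved with the group as well, at 0.0768 to 0.107 in diapause, -0.0862 to 0.0515 in mated and -0.143 to 0.005 in CO2-treated queens.

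In all, edgeR called 139 genes higher and 77 lower in diapause than in mated queens, 216 of 3793, and 51 with the line as block. The count was 319 without the 2 shallow libraries and 1192 without these and diapause replicate 1. Leaving out diapause replicate 1 alone gave 916, and founder post CO2 replicate 1, 326. Lower counts followed from leaving out mated replicate 1 (125), 3 (110), 4 (98) or 5 (99), or diapause replicate 2 (91), 3 (108), 4 (92) or 5 (107). The 2 groups did not overlap in 115 genes, 3.03%, where chance gives 0.794%.

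Queens sampled 24 h after CO2 were compared with mated queens of the same age. Vitellogenin-6-like (LOC100643258) had a log2 fold change of -4.26 ± 0.94 (SE, n = 5 and 5; edgeR adjusted p = 0.0343). Its mean was 85.7 ± 42.3 CPM (SD) after CO2 and 1645 ± 2141 in mated queens, where single queens ran from 48.6 to 4952. The trehalose transporter Tret1-like gene LOC100644462 had -3.03 ± 0.69 (0.0467), hydroxymethylglutaryl-CoA synthase 1-like (LOC100649840), of the mevalonate pathway, -2.02 ± 0.40 (0.0225), and the fatty acyl-CoA reductases LOC100647284 and LOC100647644 -4.35 ± 0.84 and -4.32 ± 0.89 (0.0208 and 0.0245), all edgeR adjusted p. Without CO2-treated replicate 4 the reductases had -5.76 and -5.79. Every one of these calls was lost with the line as block, with adjusted p of 0.129 for vitellogenin, 0.0919 for the transporter and the synthase, and 0.0703 for both reductases. The calls of the synthase and the reductases were lost without mated replicate 3 or 4 or CO2-treated replicate 1, 2 or 5, that of vitellogenin without mated 3 or 4 or any CO2-treated queen, and that of the transporter without mated 3, 4 or 5, CO2-treated 1, 2, 4 or 5, diapause 2, founder post CO2 4 or 5 or founder post diapause 2 or 5.

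Of 3 yolk and storage proteins 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.000515; adjusted p = 0.0215 with an estimated correlation, where the call held). The 7 immune effectors and receptors, a list that also held the inhibitor cactus-2, had 0 calls, 3 lower adjusted over the list alone, and a median of -1.15 (camera 8.93e-05, or an adjusted p of 0.0215 with an estimated correlation, where it held too). By fry, which asks whether members changed on balance and not whether they differ from other genes, both lists had an adjusted p of 0.0667. Gut markers had a median of 1.21 over 19 genes with 0 calls, also over the list alone (camera 8.93e-05; adjusted p = 0.366 with an estimated correlation). Oxidative phosphorylation had a median of 0.10 over 37 genes with 0 calls, also over the list alone (camera 0.248, or 0.000484 with the line as block, in the direction higher; adjusted p = 0.963 with an estimated correlation). Of 30 oenocyte and epidermis markers 3 fell, or 8 adjusted over the list alone (camera adjusted p = 0.00357, or 0.329 with an estimated correlation). All 3 were fatty acyl-CoA reductases. Without the 2 shallow libraries and diapause replicate 1, 1 of these markers rose and 6 fell, while 1 member of the immune list fell. EdgeR called 0 genes higher and 15 lower after CO2, against 172 at an unadjusted p under 0.05 and 3 higher and 39 lower by DESeq2. The count was 0 with the line as block, 39 without the 2 shallow libraries and 59 without these and diapause replicate 1. It was 41 without mated replicate 2 and 23 without diapause replicate 1, 9 without mated replicate 5, and 0 without mated replicate 3 or 4 or CO2-treated replicate 1, 2 or 5. The groups did not overlap in 37 genes, 0.9755%, close to the chance share of 0.794%.

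Diapause and CO2 treatment were compared directly. Vitellogenin-6-like (LOC100643258) was higher in diapause by 5.91 ± 1.01 on the log2 scale, with 5139 ± 3446 CPM (SD, n = 5) against 85.7 ± 42.3, and each diapause queen exceeded each CO2-treated queen. Cryptochrome-1-like (LOC100647270) was higher by 2.55 ± 0.44, larval cuticle protein LCP-17-like (LOC100643233) by 3.60 ± 0.73, and the Tret1-like trehalose transporter LOC100646027 by 2.60 ± 0.51. Trehalase-like (LOC100646078), which splits the blood sugar trehalose, had -1.83 ± 0.44, cytochrome P450 305a1-like (LOC100647578) -2.10 ± 0.36 and the alpha-methyldopa hypersensitive protein-like gene (LOC100648451) -3.49 ± 0.75, or -2.25 without CO2-treated replicate 3. The edgeR adjusted p of these genes ran from 0.00175 to 0.0178, and the calls held with the line as block. The call of trehalase was lost without CO2-treated replicate 1 or 2 or diapause replicate 2, 3 or 5. The block ended the call of the venom serine protease 34-like gene (LOC100644867, log2 -1.96, edgeR adjusted p = 0.0285, block 0.0517), as did leaving out CO2-treated 1 or 4 or diapause 2, 3, 4 or 5.

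The proteasome list had 0 calls of 27, over the list alone either, and a median of -0.61 (camera adjusted p = 4.67e-05), and oxidative phosphorylation 0 of 37 and -0.39 (0.00182). Of 30 oenocyte and epidermis markers 2 rose and 2 fell, 4 and 4 adjusted over the list alone (camera 0.00684). The 2 that fell were fatty acyl-CoA reductases. Of 20 cytochrome P450s and UDP-glycosyltransferases 2 fell, 2 adjusted over the list alone (camera 0.0446), and of 19 fatty acid genes 1 rose, 1 and 2 fell over the list alone, while the list tested lower (camera 0.0223). Secretion (0.0223) and antioxidant genes (0.0360) tested lower with 0 calls. Gut markers had 0 calls of 19, also over the list alone, and a median of -1.06 (camera 0.0604, or 0.0359 with the line as block). Each of these lists had an adjusted p = 0.618 with an estimated correlation. Without the 2 shallow libraries and diapause replicate 1, 16 of 27 proteasome, 15 of 37 oxidative phosphorylation, 4 of 12 secretion and 5 of 19 gut genes were lower and 0 higher, in a comparison whose 3' to 5' coverage also did not overlap, and higher and lower genes numbered 1 and 8 of 25 for antioxidant, 5 and 14 of 30 for oenocyte, 1 and 7 of 20 for cytochrome P450 and UDP-glycosyltransferase and 1 and 8 of 19 for fatty acid genes. Of 16 insulin, TOR and FOXO genes 2 rose, and 4 adjusted over the list alone. Both were ribosomal protein S6 kinases, but not the beta-1-like gene (LOC100646461, log2 0.19 ± 0.44, not called): delta-1-like LOC100649545 (log2 1.35 ± 0.29), not called without CO2-treated replicate 2 or diapause replicate 5, and the alpha-5-like LOC100647851 (1.38 ± 0.42, edgeR adjusted p = 0.0498, block 0.0566). The latter was called only when the queen left out was mated 2, CO2-treated 3, diapause 1, founder post CO2 1 or 3 or founder post diapause 1, 2 or 3.

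EdgeR called 214 genes higher and 30 lower in diapause than after CO2, 244 in all, and 130 with the line as block. The count was 305 without the 2 shallow libraries and 1383 without these and diapause replicate 1. It rose to 1091 without diapause replicate 1, 367 without founder post CO2 replicate 1 and 378 without founder post diapause replicate 1. It was 119 without mated replicate 4, 125 without founder post CO2 replicate 5, 121 without founder post diapause replicate 5, 65, 69, 64 and 68 without CO2-treated replicates 1, 2, 4 and 5, and 72, 84, 75 and 77 without diapause replicates 2 to 5. The groups did not overlap in 101 genes, 2.66% (chance share 0.794%).

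Genes apart in diapause from each of the 4 other groups numbered 118, of which 109 were higher and 9 lower. Those with the smallest adjusted p among the higher were DGCR8-like (LOC100642999), a partner in microRNA processing, with log2 1.81 ± 0.31 against mated queens, the cell growth regulator with RING finger domain (LOC100643334, 1.54 ± 0.26), cryptochrome-1-like (LOC100647270), isocitrate dehydrogenase-like (LOC100642724, 1.38 ± 0.24) and the cell division control protein 6 homolog (LOC100644374). Named genes lower in diapause were LOC100648451, the fatty acyl-CoA reductase LOC100648083, a RING finger protein-like gene (LOC100642506, -1.39 ± 0.37, block adjusted p 0.0756 in edgeR) and the unnamed LOC100643414 and LOC100650155. With the line as block 18 were higher and 1 lower, and without the 2 shallow libraries 143 were apart, or 947 without these and diapause replicate 1. Leaving out diapause replicate 1 gave 725, founder post CO2 replicate 1, 183, and founder post diapause replicate 1, 194. Lower counts came without mated replicates 1 (65), 3 (55), 4 (50) and 5 (55), CO2-treated 1 (45), 2 (43), 4 (43) and 5 (47), diapause 2 (41), 3 (48), 4 (41) and 5 (45), founder post CO2 5 (67) and founder post diapause 5 (65).

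The responses to diapause and to CO2, each against mated queens, shared 8 genes, all lower, where 0.305 would be shared by independent lists, and 1 gene, the C20orf4-like LOC100649756, was called in opposite directions, higher in diapause and lower after CO2. The shared genes included the fatty acyl-CoA reductases LOC100647284 and LOC100647644 and retinol dehydrogenase 10-A-like (LOC100647225, log2 -2.20 ± 0.41 in diapause and -2.00 ± 0.40 after CO2). Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.249 and a Spearman rho of 0.103. Because both comparisons used the same mated queens, 50 simulated draws with no change gave a mean r of 0.501 and 0 shared genes. The covariances were 0.120 simulated and 0.103 measured. In every draw independent lists would also have shared 0, so the simulated 0 is no yardstick for the 8 shared genes. With the mated queens split between the comparisons in 20 ways, the median r was -0.0619, from -0.236 to 0.160. The median number of shared genes was 0, from 0 to 10. The overlap was 0 with the line as block, 23 without the 2 shallow libraries, 27 without these and diapause replicate 1, 26 without mated replicate 2, 5 without mated replicate 5, and 0 without mated 3 or 4 or CO2-treated 1, 2 or 5. Without mated replicate 2, r was 0.448, and without diapause replicate 1 it was 0.108.

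Egg-laying founders a month after the cold were compared with queens at its end. Vitellogenin-6-like (LOC100643258) fell by 8.06 ± 1.11 on the log2 scale (SE, n = 5 and 5), from 5139 to 19.2 ± 5.68 CPM (SD), and PEPCK, the entry enzyme of gluconeogenesis, by 6.18 ± 1.14, from 10400 to 143. Serine protease inhibitor 3-like (LOC100651307) rose by 7.70 ± 1.16, from 25.2 to 5263 CPM, or by 9.11 without diapause replicate 1 and 6.36 without founder post diapause replicate 1. Maelstrom (LOC100644702), of the piRNA pathway of the germ line, rose by 4.38 ± 0.59 and cortex-like (LOC100652120) by 3.85 ± 0.57. Cryptochrome-1-like (LOC100647270) fell by 3.82 ± 0.46, fatty acyl-CoA reductase 1-like (LOC100642508) by 5.46 ± 0.72 and the insulin-like receptor (LOC100650952) by 3.10 ± 0.58. Each of these 8 genes had an edgeR adjusted p of at most 9.88e-05.

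Further genes that rose were 15-hydroxyprostaglandin dehydrogenase-like (LOC100643900, log2 5.55 ± 0.73), takeout-like (LOC100643577, 4.01 ± 0.68), exuperantia-like (LOC100646270, a maternal factor, 2.96 ± 0.52) and superoxide dismutase (LOC100646662, 2.14 ± 0.44). Hexamerin-like LOC100650745 had -2.91 ± 1.14 (edgeR adjusted p = 0.0231) and lost its call without founder post diapause replicate 1 or 5. Forkhead box protein O-like (LOC100643217) had -1.45 ± 0.60 (0.0310), and its call was lost without diapause replicate 1 or 3 or founder post diapause replicate 1, 3, 4 or 5. Juvenile hormone epoxide hydrolase 1-like (LOC100648328), which breaks down juvenile hormone, had 0.99 ± 0.50 (edgeR adjusted p = 0.0685; 0.0329 with the line as block; called without diapause replicate 1), with 1891 CPM in diapause replicate 1 and 367.8 to 433.6 in the other 4 diapause queens.

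**Figure D3:**
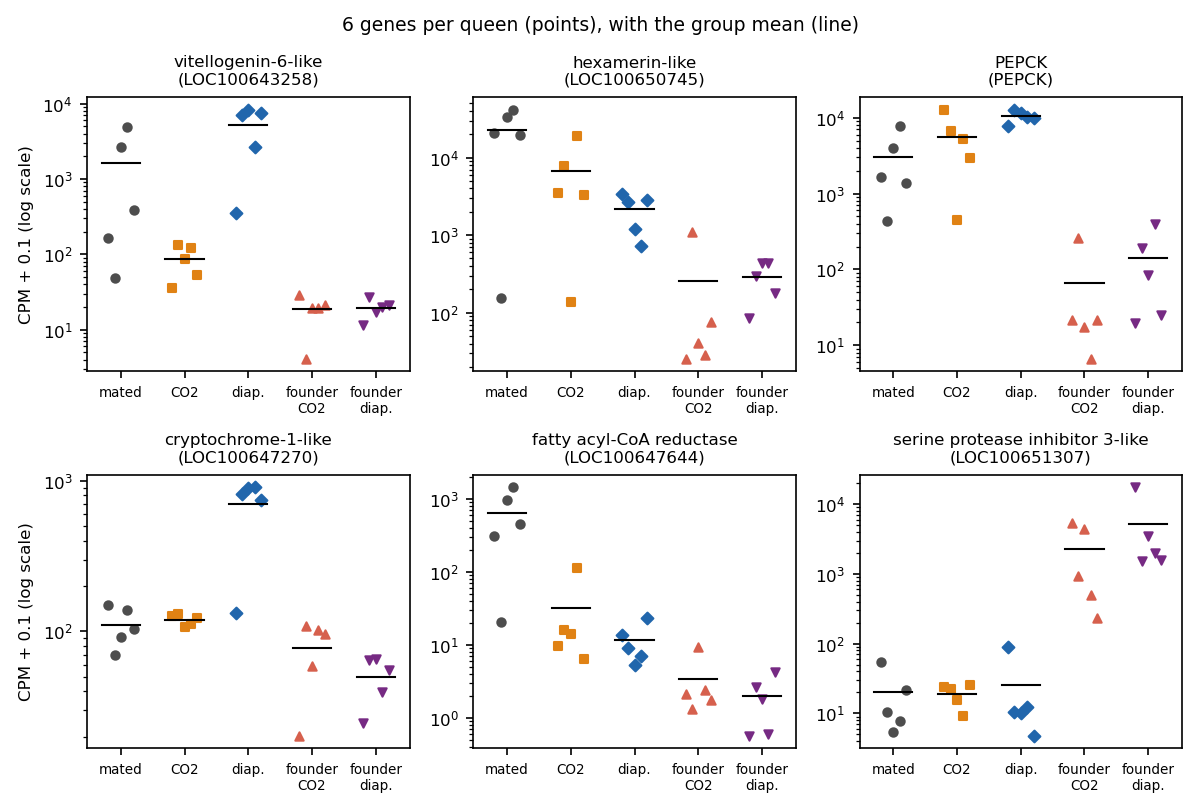
Points are single queens (n = 5 per group) and lines group means, for 6 genes, on a log axis of CPM plus 0.1. Vitellogenin-6-like lies highest in diapause (mean 5139 CPM) and lowest in founders (18.6 and 19.2). The serine protease inhibitor lies highest in founders (2313 and 5263).

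Of 37 oxidative phosphorylation genes 35 rose and 0 fell (camera adjusted p = 2.40e-07), of 27 proteasome genes 23 rose and 0 fell (2.40e-07), of 12 genes of endoplasmic reticulum secretion all 12 rose (0.00498), and of 25 antioxidant enzymes 19 rose and 2 fell (0.00530), with the same counts adjusted over the list alone. These camera calls were lost, each at adjusted p = 0.638 with an estimated correlation. The 3' to 5' coverage ran from -0.129 to 0.0827 in these founders, against 0.0768 to 0.107 in diapause queens. Across all genes tested, log2 fold changes in this comparison also went down with gene length (Spearman rho -0.465). The lists were not tested with that trend removed, so a part of gene length in their counts stays open. Examples of list members that rose were an NADH dehydrogenase beta subunit (LOC100647466, log2 2.93 ± 0.59, or 4.06 without diapause replicate 1), proteasome subunit alpha type-4-like (LOC100651366, 2.70 ± 0.45), protein disulfide-isomerase A3-like (LOC100648662, 2.22 ± 0.39) and glutathione S-transferase omega-1-like (LOC100650118, 2.61 ± 0.47). Insulin, TOR and FOXO signalling had 2 higher and 11 lower of 16, the same over the list alone, among them the ribosomal protein S6 kinase alpha-5-like gene LOC100647851 (-2.80 ± 0.44); its camera adjusted p was 0.0518, or 0.04998, just under the threshold, with the line as block (adjusted p = 0.638 with an estimated correlation).

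No further list was called by camera in this comparison. Counts higher and lower were 11 and 5 of 19 for fatty acid and triglyceride synthesis, with elongase LOC100652206 at log2 3.01 ± 0.42 and desaturase LOC100649922 at -2.53 ± 0.37. They were 7 and 1 of 13 for lipid breakdown (6 and 1 adjusted over the list alone), 10 and 10 of 29 for glycogen, trehalose and polyol metabolism, 10 and 2 of 19 for heat shock proteins, and 8 and 4 of 20 for cytochrome P450s and UDP-glycosyltransferases. Juvenile hormone and ecdysteroid genes had 5 and 3 of 9, immune effectors and receptors 2 and 3 of 7 (median 0.25, mean -0.32), cell cycle genes 7 and 1 of 13 (5 and 1 over the list alone), and ribosomal proteins 6 and 1 of 13 (5 and 1). Cuticle genes had 2 and 1 of 4, yolk and storage proteins 0 and 2 of 3, circadian clock genes 0 and 2 of 2, and chemosensory genes 1 and 1 of 2. Where no second pair is given, counts adjusted over the list alone were the same. Fatty acyl-CoA reductases, counted as before, had 6 higher and 4 lower of 14.

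Among markers of other cell types, 12 of 19 gut genes rose and 0 fell, 9 adjusted over the list alone, with a median of 3.36 (camera adjusted p = 0.0673, or 0.04998 with the line as block; 0.638 with an estimated correlation). Muscle had 4 higher and 4 lower of 10, with paramyosin-like (LOC100644720) at log2 -2.57 ± 0.61. Germ line and ovary had 3 and 2 of 5, oenocyte and epidermis 14 and 9 of 30, hemocyte 0 and 1 of 3 (0 over the list alone), and neuron 6 and 5 of 14, with a median of 0.64, a mean of -0.37 and a camera direction of lower. The medians of muscle, gut, neuron and ovary lists were all above 0.

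EdgeR called 1526 genes higher and 1541 lower, 3067 of 3793 or 80.9%, with 2980 of them also called with the line as block. Without the 2 shallow libraries the count was 3125, and without these and diapause replicate 1, 3212. The groups did not overlap in 1848 genes, 48.7%, against a chance share of 0.794%. The count rests on a table whose intervals were chosen by an unknown rule, and it says nothing of genes outside it.

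Founders a month after CO2 were compared with queens 24 h after it. Serine protease inhibitor 3-like (LOC100651307) rose by 6.91 ± 1.13 on the log2 scale (SE, n = 5 and 5), from 19.1 to 2313 CPM, LOC100643900 by 6.40 ± 0.76, maelstrom (LOC100644702) by 5.49 ± 0.63 and exuperantia-like (LOC100646270) by 3.23 ± 0.53. PEPCK fell by 6.42 ± 1.16, from 5582 to 65.3 CPM, and hexamerin-like LOC100650745 fell by 4.73 ± 1.24, from 6738 to 253. Both founder means rest on founder post CO2 replicate 2, with 259.7 and 1096 CPM where the other 4 had at most 21.7 and 76.07, and without it the log2 fold changes were -8.38 and -7.31. The other hexamerin-like gene (LOC100650380) rose by 1.72 ± 0.48, a call lost without founder post CO2 replicate 3. A Tret1-like trehalose transporter (LOC100644978) rose by 5.14 ± 0.66 and proliferating cell nuclear antigen (LOC100646427), the sliding clamp of DNA replication, by 1.66 ± 0.33. The edgeR adjusted p of these 9 genes was at most 0.0142.

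Vitellogenin-6-like (LOC100643258) was not called, at -2.21 ± 0.86 (edgeR adjusted p = 0.0562, DESeq2 0.0203), with 85.7 and 18.6 CPM, and was called without mated replicate 1, 2 or 4 or diapause replicate 1. Superoxide dismutase (LOC100646662) had 1.15 ± 0.43 (0.0480, block 0.0905) and the insulin-like receptor (LOC100650952) -1.40 ± 0.55 (0.0559, block 0.0462), both by edgeR. The dismutase was called only when the queen left out was mated 2, diapause 1, founder post CO2 2, 4 or 5 or founder post diapause 1, and the receptor was called without founder post CO2 5. Of 27 proteasome genes 15 rose and 0 fell, 17 adjusted over the list alone (camera adjusted p = 6.73e-05), and of 37 oxidative phosphorylation genes 6 rose, 0 adjusted over the list alone (0.00234). Cell cycle genes had 6 higher and 1 lower of 13, 9 and 1 adjusted over the list alone (0.0188), with the spindle and kinetochore-associated protein 1-like gene (LOC100645784) at 4.99 ± 0.82, or 3.24 without founder post CO2 replicate 1. Ribosomal proteins had 4 higher of 13, 5 over the list alone (0.0246), germ line and ovary markers 3 of 5, 3 over the list alone (0.0299), and secretion genes 0 of 12 (0.0473). All of these lists had an adjusted p = 0.672 with an estimated correlation. Founder post CO2 replicates 1 and 3, which lay apart on the first component, had the highest list scores (the mean over members of log2 CPM less the mean of all 25 libraries) of this group: 1.54 and 1.26 for oxidative phosphorylation, 1.61 and 1.29 for ribosomal proteins and 1.24 and 0.89 for secretion. The other 3 founders had -0.36 to -0.01, -0.49 to 0.09 and -0.25 to 0.17, against -1.02 to 0.12, -0.97 to 0.03 and -0.53 to 0.21 in CO2-treated queens. Replicates 1 and 3 also had the highest 3' to 5' coverage of these founders, 0.0675 and 0.0598, against -0.140 to -0.104. Muscle markers had 1 higher and 4 lower of 10 and gut markers 4 higher of 19, the same adjusted over the list alone, with neither called by camera (0.201 and 0.0552). Without the 2 shallow libraries and diapause replicate 1, 8 proteasome, 0 oxidative phosphorylation, 3 cell cycle, 2 ribosomal and 3 germ line and ovary genes rose.

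EdgeR called 560 genes higher and 515 lower, 1075 or 28.3%, and 338 and 413 with the line as block. The count was 600 without the 2 shallow libraries and 670 without these and diapause replicate 1. It was 591, 561 and 544 without CO2-treated replicates 1, 2 and 3, and 491 and 552 without founder post CO2 replicates 1 and 3. The groups did not overlap in 606 genes, 15.98% (chance share 0.794%).

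**Figure D4:**
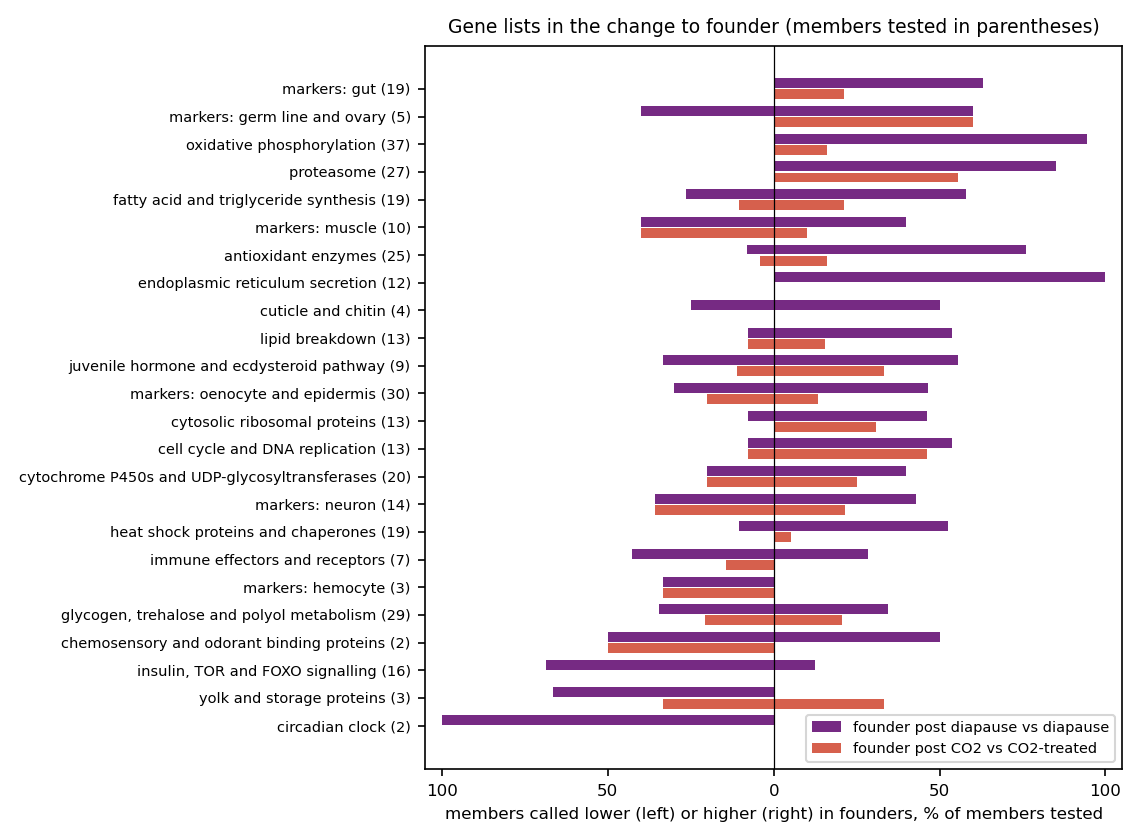
Bars give the percentage of each list's tested members (number in parentheses) called lower (left) or higher (right) in founders, after diapause (purple) and after CO2 (orange). In oxidative phosphorylation 35 of 37 members rose after diapause and 6 after CO2.

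The changes to founder by the 2 routes used separate libraries. They shared 977 called genes in the same direction, 495 higher and 482 lower, where independent lists would share 225 and 209, and 0 were called in opposite directions. The shared genes with the smallest adjusted p included the peroxisomal acetyl-spermine oxidase-like gene (LOC100649586, log2 3.83 ± 0.46 after diapause and 4.75 ± 0.48 after CO2), maelstrom, cortex-like (LOC100652120), the organic cation transporter-like gene (LOC100648294, -4.54 ± 0.49 and -3.27 ± 0.46), ABC transporter G member 1-like (LOC100644985, -4.29 ± 0.48 and -3.01 ± 0.45) and esterase FE4-like (LOC100647220, -2.50 ± 0.42 and -2.84 ± 0.42). Across genes r was 0.825 and rho 0.855, and 90.3% of genes had the same sign. The overlap was 683 with the line as block, 535 without the 2 shallow libraries and 584 without these and diapause replicate 1. It was 535, 501 and 484 without CO2-treated replicates 1, 2 and 3, and 445 and 492 without founder post CO2 replicates 1 and 3.

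**Figure D5:**
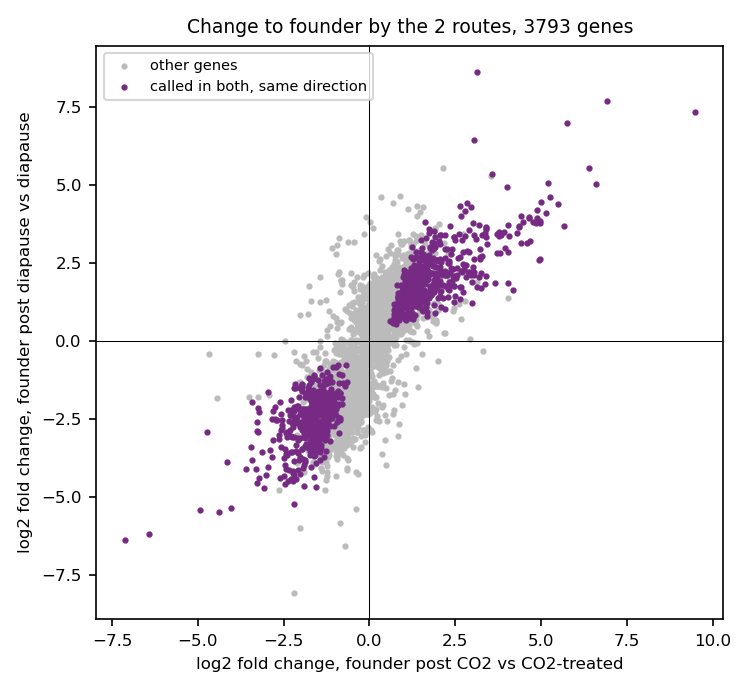
Each point is 1 of 3793 genes, with its log2 fold change from CO2 treatment to founder (x) and from diapause to founder (y), and 977 purple points called in both in the same direction. The cloud follows the diagonal, with r = 0.825 across genes.

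A test of the difference between the routes called 92 genes, 3 with a higher and 89 with a lower value on the diapause route, and 3 with the line as block, all lower: LOC100649756, LOC100648499 and LOC100649373. Vitellogenin-6-like (LOC100643258) differed by -5.86 (edgeR adjusted p = 0.0230), cryptochrome-1-like (LOC100647270) by -3.18 ± 0.60 (0.0110, block 0.0603) and coagulation factor X-like (LOC100649373), a serine protease-like gene, by -3.95 ± 0.69 (0.00717, block 0.0396). Elongase 6-like (LOC100643669) differed by 3.10 ± 0.85 (0.0495, block 0.0739; 4.77 without diapause replicate 1), a call kept only when the queen left out was CO2-treated 3, diapause 1, founder post CO2 1 or 3 or founder post diapause 2. Oxidative phosphorylation (camera adjusted p = 9.28e-08), proteasome (1.33e-06), antioxidant (0.00215), secretion (0.00552), oenocyte (0.0110) and fatty acid lists (0.0382) tested higher on the diapause route, each with an adjusted p of 0.445 with an estimated correlation. Of these lists' members, 0 of 37, 0 of 27, 0 of 25, 0 of 12, 1 of 30 and 1 of 19 were called, adjusted over the list alone as well. Without the 2 shallow libraries and diapause replicate 1, 20 of 37, 15 of 27, 10 of 25, 6 of 12, 11 of 30 and 6 of 19 were higher, and 0, 0, 1, 0, 2 and 2 lower. Gut markers had 0 calls of 19 and a median of 2.36 (camera 0.208; 4 higher without these 3 libraries).

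DESeq2 called 484 genes in that test, 1038 had an unadjusted p under 0.05, and the count was 246 without the 2 shallow libraries and 1388 without these and diapause replicate 1. It rose without diapause replicate 1 (1005), CO2-treated 3 (183), founder post CO2 1 (784) and 3 (553) and founder post diapause 2 (220). It fell without mated replicates 1 (57), 3 (61) and 4 (41), CO2-treated 1 (9), 2 (21), 4 (9) and 5 (9), diapause 2 (16), 3 (35), 4 (22) and 5 (11), founder post CO2 2 (60), 4 (13) and 5 (9), and founder post diapause 3 (53), 4 (10) and 5 (60).

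The founders of both routes were compared last, and they also differ in age. Vitellogenin-6-like (LOC100643258) had 19.2 and 18.6 CPM, a log2 difference of 0.05 ± 0.84, PEPCK 1.13 ± 0.93 (3.10 without founder post CO2 replicate 2, not called either) and chloroplastic-like superoxide dismutase (LOC100642760) 1.69 ± 0.58, none of them called. Oxidative phosphorylation tested higher in founders after diapause (median 0.47, camera adjusted p = 8.58e-11; adjusted p = 0.518 with an estimated correlation), as did proteasome (0.000355; adjusted p = 0.655 with an estimated correlation) and antioxidant genes (0.000907; adjusted p = 0.518 with an estimated correlation). Muscle markers tested higher (camera 0.00535; adjusted p = 0.0562 with an estimated correlation) although their median was -0.02 and their mean 0.45, and 2 of 10 were higher adjusted over the list alone. Germ line and ovary markers tested lower (0.0334; adjusted p = 0.518 with an estimated correlation), and cuticle (0.0171; adjusted p = 0.393 with an estimated correlation) and secretion genes (0.0202; adjusted p = 0.720 with an estimated correlation) higher. No member of these lists was called, and over the list alone only the 2 muscle genes were. Gut markers had a median of 1.295 and a mean of 0.821 over 19 genes, with 0 calls, also over the list alone, and a camera direction of lower (adjusted p = 0.995; 0.998 with an estimated correlation).

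EdgeR called 0 genes between the founders, with 273 at an unadjusted p under 0.05, 3 higher and 5 lower by DESeq2, 0 with the line as block and 0 without the 2 shallow libraries or these and diapause replicate 1. Leaving out founder post CO2 replicate 1 gave 4 genes, founder post CO2 replicate 2 or 3 gave 1, and founder post diapause replicate 1 gave 1. The groups did not overlap in 11 genes, 0.290%, below the chance share of 0.794%. Within founders the libraries varied along another line: founder post CO2 replicates 1 and 3 lay at 104 and 82.8 on the first component and the other 3 at 5.85 to 14.1, while founders post diapause lay at 32.5 to 101.2. In simulated counts with the dispersions of all 25 libraries, 82% of genes changed 4-fold and 24% of those changed 2-fold between the founders were recovered. The simulation drew each gene independently, without the variation that founders share across genes. Recovery in the real libraries may therefore be lower.

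The positions of the main genes, on a genome build not given in the sources used here, were 4550502 to 4556727 of scaffold Group13.5 for vitellogenin-6-like (LOC100643258), 8965993 to 8972653 of Group10.1 for cryptochrome-1-like (LOC100647270), 600027 to 605477 of Group3.4 for PEPCK, 1608626 to 1612476 of Group16.3 for hexamerin-like LOC100650745, and 3571 to 6195 of GroupUn943 for serine protease inhibitor 3-like (LOC100651307).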

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

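Of the tests in this part, those on tissue shares in founders, on muscle or gut tissue in diapause replicate 1, and all on the pair of shallow libraries were chosen only after the result was seen. Chance alone marks about 1 in 20 groups by the gap rule used for single libraries, and 5 of the 90 groups tested, 5.56%, were marked.

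By that rule, in which the most extreme of 5 libraries lies apart by most of the group's range, juvenile hormone epoxide hydrolase 1-like (LOC100648328) had 1891 CPM in diapause replicate 1, where the next library had 434. Hexamerin-like LOC100650745 had 1096 CPM in founder post CO2 replicate 2, with 76.1 in the next library. PEPCK had 260 CPM in that same library, with 21.7 in the next. Superoxide dismutase (LOC100646662) had 14530 CPM in founder post CO2 replicate 3, with 5760 in the next. The hemocyte list score was -0.59 in founder post CO2 replicate 1, with -0.11 in the next.

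The change to founder differed between the routes in 92 genes by an edgeR interaction test. The log2 differences (diapause route less CO2 route) were 4.26 for LOC100645985, 2.34 for neurexin-2-alpha-like LOC100646013, 3.10 for elongase LOC100643669, -4.98 for LOC100649756, -5.84 for LOC100648499, -3.95 for coagulation factor X-like LOC100649373, -3.16 for LOC100648836, -3.18 for cryptochrome-1-like LOC100647270 and -5.86 for vitellogenin-6-like LOC100643258.

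Founders after diapause parted from diapause queens in 3067 genes of 3793. With a trend on gene length removed from each library, edgeR called 2570, of which 2283 were also called before, so a length trend does not carry the pattern alone, although genes that rose were shorter (median length 2092 against 4938). With the 3' to 5' coverage of each library as a covariate 3254 were called, 2935 of them shared. The covariate was fitted from differences within groups, while coverage also moved between these groups. RNA integrity is therefore not settled by this count. A lower share of fat body would raise the markers of other tissues, and all 4 medians lay above 0. The gut and neuron medians lay 2.72 apart (SE 0.817). Other tissues need not remain in equal amounts, so this gap decides neither way. The change of age, temperature and feeding with egg laying stays open as the biological explanation and was not tested apart.

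Diapause replicate 1 stood apart from the other 4 diapause libraries. On an axis from mated and CO2-treated queens at 0 to the other diapause queens at 1 it lay at -0.225, beside mated and CO2-treated libraries at -0.201 to 0.410, and the other diapause libraries at 0.640 to 1.07. Thinned to 534806 counts, it had a chi-square per degree of freedom of 42.1 to 72.6 with the other diapause libraries. With CO2-treated libraries the value was 10.98 to 19.8, except for 50.4 with the shallow CO2-treated replicate 3. A wrong label is thus a candidate explanation. Of 504 genes higher in the other diapause queens, this library lay within the mated and CO2-treated range in 401, below it in 82 and above it in 21. Of 350 genes lower in them, it lay within that range in 255, above it in 84 and below it in 11. Against a wrong label, the library's 3' to 5' coverage of 0.107 lay with the other diapause libraries, at 0.0768 to 0.101. That coverage also lay above all mated and CO2-treated libraries, of which the highest had 0.0515. Gut tissue may add to the difference, since its gut score exceeded the highest of the other 4 by 1.68, and its muscle score was 0.675 against at most 0.1885. Both scores also lay within the range of CO2-treated libraries. Its gut score was 0.827, in a range of -0.975 to 1.84, and the muscle range was 0.214 to 0.740. A CO2-treated library could have such scores as well, so they do not tell gut tissue from a wrong label. A queen whose diapause ended early also stays open, and was not tested.

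Mated replicate 2 and CO2-treated replicate 3 were closer to each other than any other pair of 300. Low depth is argued against, since with all libraries thinned to 534806 counts the next pair still stood at 6.01, against 2.43 for this pair. Reads of the other libraries are argued against by 205 genes in which both lay outside the range of the other 23. The median pair had 0 such genes, and the highest other pair, founder post CO2 replicate 1 with founder post diapause replicate 1, had 626. The same RNA in both libraries cannot be told apart from a close resemblance, because 2.43 lies above the value of 1 of counting noise but below every pair of queens of a group. The labels gave the libraries different groups and different genetic lines, and no biological explanation was tested.

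Other splits of the libraries were run for each count, 100 splits per comparison. For diapause against mated queens 5 splits, the real one included, gave at least the real 216 genes, so chance cannot be excluded. The highest other gave 1236, several times the real count, with diapause replicate 1 placed among mated queens 1, 3, 4 and 5, which points to a structure of the samples. For diapause against CO2-treated queens 5 splits gave at least 244, so chance cannot be excluded, and the highest other gave 1401, with diapause replicate 1 among CO2-treated queens 1, 2, 4 and 5. For CO2-treated against mated queens 4 splits gave at least 15, just under the share of 0.05. The line as block gave 0 genes, and 1 of 14 splits that part as many same-line pairs gave at least 15. Chance is therefore not excluded. The highest other gave 41, with mated replicate 2 and CO2-treated replicate 2 exchanged, which also points to a structure of the samples. For founders post diapause 1 split, the real one, gave 3067, and for founders post CO2 1 gave 1075, so chance can be excluded for both, with highest others of 2684 and 363. Between the founders the real count was 0, which all 100 splits reach by construction, so their number says nothing of chance. The highest other gave 2121, with founder post CO2 replicates 1 and 3 and founder post diapause replicates 1, 3 and 4 set against the rest, a structure of the samples that does not follow the route. For genes apart in diapause 1 split, the real one, gave 118, with a highest other of 0. These splits shuffled all 25 libraries and so mixed founders with other queens in the groups, which makes other high counts unlikely. They do not test diapause against mated and CO2-treated queens alone, so chance is not excluded for these genes. For the route difference 3 splits gave at least 92, under the share of 0.05. These splits exchanged labels within a stage and so also undid any plain difference between diapause and CO2-treated queens. They do not test the route difference alone, so chance is not excluded for it. The line as block left 3 genes. The highest other split gave 1803, several times the real count, which points to a structure of the samples. That split exchanged CO2-treated replicate 3 with diapause replicate 5 and founder post CO2 replicate 1 with founder post diapause replicate 2.

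Splits that part as many pairs of the same line as the real one were too few for a share under 0.05. They gave at most 565 genes for diapause against mated queens (12 splits, 1 of them at least 216), 22 for CO2-treated against mated queens (14 splits, 1 at least 15), 237 for diapause against CO2-treated queens (11 splits, 0 at least 244), 2684 and 336 for the founder changes (12 and 11 splits, 0 as large) and 1825 between founders (11 splits). The remaining splits part fewer or more of these pairs.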

How the results depend on the processing

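The alternatives that left out the 2 shallow libraries, or these and diapause replicate 1, or that took the main scaffold only or the top interval per gene, were chosen only after the result was seen. So were the single-queen runs of both overlaps, and the block run of the overlap of the responses to diapause and CO2. The block run of the overlap of the changes to founder was fixed in advance. Relative log expression factors, the main scaffold and the top interval kept every count of genes within 1.5 times, and between scalings the median log2 moved by at most 0.0492. Each of these scalings centres on the bulk of the table's genes, so their likeness does not test that centring. In founders post diapause against diapause queens, where 80.9% of genes were called, higher and lower are relative to it. The cause of a change was not tested except that fewer libraries or a block leave fewer degrees of freedom.

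DESeq2 gave 457, 42, 509 and 8 genes for diapause against mated, CO2-treated against mated, diapause against CO2-treated and founder against founder, 265 apart in diapause and 484 for the route difference. The line as block gave 51, 0 and 130 for the first 3 of these, 19 apart, 3 for the routes and 0 for the overlap of both responses, and changed no other count beyond 1.5 times. The compared groups alone gave 102, 0 and 24, and 378 for founders post CO2. No low-count filter gave 143 for diapause against CO2-treated, 77 apart and 55 for the routes.

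Without the 2 shallow libraries 39 genes were called for CO2-treated against mated, 600 for founders post CO2 and 246 for the routes, and the overlaps were 23 and 535. Without these and diapause replicate 1 the counts were 1192, 59 and 1383, 670 for founders post CO2, 947 apart, 1388 for the routes, and overlaps of 27 and 584. With the mated queens split, the median overlap of both responses was 0 and their median correlation -0.0619, from -0.236 to 0.160. The shared controls had added to the correlation by construction.

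Over single queens left out, counts ran from 91 to 916 for diapause against mated, 0 to 41 for CO2-treated against mated, 64 to 1091 for diapause against CO2-treated, 2769 to 3160 for founders post diapause, 491 to 1342 for founders post CO2, 0 to 4 between founders, 41 to 725 apart and 9 to 1005 for the routes. The overlaps ran from 0 to 26 and from 445 to 1235, and the correlations from 0.108 to 0.448 and from 0.750 to 0.854.

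Of the list tests of the 6 comparisons between groups 35 were called by camera and 2 with an estimated correlation, and of those of the route difference 6 and 0. Over the 132 list results between groups, an estimated correlation kept 99 and ended 33 and the block kept 125, ended 3 and added 4. The test fry asks another thing, whether members changed on balance, and passed 24 lists. Over 234 named gene results, the block kept 193, ended 38 and added 3, DESeq2 kept 225, ended 1 and added 8, and relative log expression kept 232 and added 2. With 1 queen left out, 5452 results stayed, 375 lost and 23 gained their call. Simulated 2-fold changes were recovered in 12% to 24% of genes, which limits what absent calls say.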

Other observations

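The tests in this part were planned before their results were seen, while the genes were picked as the members of the germ line list that rose. Genes known from ovary were higher in founders: piwi-like (LOC100646008), exuperantia-like (LOC100646270) and vitellogenin receptor-like (LOC100649042) all rose in both changes to founder, at log2 2.71, 2.96 and 2.83 after diapause and 3.29, 3.23 and 3.72 after CO2. Founder post diapause replicate 1 was an exception, with 42.29, 297 and 102.9 CPM for the 3 genes in that order, against at most 85.06, 265.4 and 427.1 in diapause queens and at least 230.1, 733.1 and 595.2 in the other 4 founders post diapause. The list's other members, nanos-like LOC100642642 and bicaudal D-related LOC100650109, had log2 -1.51 and -2.76 after diapause, both called, and 0.49 and -0.35 after CO2, neither called.

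A hypothesis is that ovary tissue remained in founder dissections, although the abdomens were eviscerated. The 3 genes would then vary together among the 10 founder libraries. Their median pairwise correlation, across deviations from group means, was 0.718, at percentile 79.8 of 10000 random triples from 492 genes that rose in both changes, whose median was 0.306. It may hold, but the value lay below the 95th percentile and above the median, so that the test decides neither way.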
